A study of Triticum aestivum with 12 samples.

How the data were processed

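Root tissue of 18-day-old wheat seedlings grown in sand was profiled on Affymetrix wheat arrays, 1 array per sample and 12 arrays in all. The arrays covered 3 genotypes (Pavon76, Pavon-TL and Null Control) under 2 water conditions, with 2 arrays in each of the 6 groups. Well water meant daily watering and water stress meant watering every second day. RNA was extracted with Trizol and labelled with biotin by the standard Affymetrix in vitro transcription protocol. The deposited values are on a log2 scale, as RMA values that the authors computed (background correction, quantile normalization between arrays and a median polish over the probes of a probe set). The version of RMA is not stated in the sources used here. The scale was checked on the values, which ran from 2.32 to 14.8, with array medians between 5.89 and 5.93.

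The value table held 61290 probe sets. The 111 Affymetrix control probe sets were left out of the tests and used only as controls, which left 61179 probe sets. No detection calls were used, so a low value is a low RMA value and not a statement that a transcript was absent. Differences of low values are understated on this scale, and no filter on dim probe sets was applied to the reported values. The number of arrays limits the precision of each value. The labels do not say whether the arrays of a group came from separate plants or cultures, so the tests measure the spread between these arrays, and that spread may be technical.

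Gene names came from the platform annotation of 2007. It gave 1 gene symbol for 1273 probe sets (2.08%), several symbols for 0 and none for 59906. These probe sets belonged to 771 genes, of which 770 matched the RefSeq gene table of the assembly IWGSC CS RefSeq v2.1. A name other than a LOC number was given for 102 genes, measured by 200 probe sets. Genes are given by name and by the LOC number of the annotation, and probe sets without a gene by their values.

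Values were fitted in R 4.3.3 with limma 3.58.1: a linear model of the 6 group means, moderated by empirical Bayes, with a contrast for each comparison. Probe sets with a Benjamini-Hochberg adjusted p below 0.05 over the 61179 probe sets were called. All p-values from limma are two-sided, and no fold threshold was applied. There were 12 comparisons: water stress against well water in each genotype and averaged over the 3 genotypes, Pavon-TL against the mean of both other genotypes (averaged over the water conditions and within each), Pavon-TL against Pavon76, Pavon-TL against Null Control, Null Control against Pavon76, and a pair of interactions. The comparisons of Pavon-TL with Pavon76 and with Null Control share the Pavon-TL arrays, so their calls were not compared with each other.

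The groups share the replicate numbers 1 and 2, and a model with the replicate number as a block was fitted as an alternative. The deviations of the arrays from their group means correlated across probe sets between 0.606 and 0.795 in 15 of 15 pairs of groups. The first principal component separated the replicate numbers and held 54.4% of the variance. By these correlations the numbers pair the samples, although the labels do not say what a number marks. The model without the block, planned beforehand, leaves the difference between the numbers in its spread. Its unadjusted p fell under 0.05 in only 1.77% to 4.28% of probe sets over the comparisons, so its counts err toward too few. The correlations and the counts of both models were first seen together, while the limit of 0.1 on the correlations had been set beforehand. The blocked value is given beside a result where it changes a call or moves a count by more than 1.5 times.

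The choices of test, groups, alternatives, gene lists and naming rule were made before the data were examined. For each comparison the rule took called probe sets with 1 gene name (other than a LOC number) and array values that did not overlap in the direction of the change, up to 10 in each direction and with 1 probe set per gene (the one with the highest mean over all arrays). For an average over genotypes or water conditions, it required the same direction in each of them instead. Where fewer than 5 passed, the 5 named genes with the smallest p were taken as values that did not pass. Up to 4 members per gene list were added in the stress, Pavon-TL and interaction comparisons. The 19 gene lists were fixed as patterns on gene symbols and their synonyms, since the annotation has no gene titles. Of these, 7 lists had at least 5 probe sets and were tested with camera (limma) at a preset correlation of 0.01, and again with an estimated correlation. A further 6 lists had 1 to 4 probe sets and were described without a set test. The other 6 had no annotated member: abscisic acid, aquaporin, DREB, CBF and ERF factors, NAC, WRKY and MYB factors, root development with auxin and brassinosteroid, and nutrient transport. Spiked control transcripts were compared between the water conditions with exact sign-flip tests over the 6 pairs of arrays with the same genotype and replicate number.

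The alternatives were a trended and robust variance prior, leaving out the dimmest 40% of probe sets by mean level, median and MAD scaling, a repeated quantile normalization, leaving out probe sets marked as cross-hybridizing, array weights, the replicate block, a fit of only the arrays compared, and leaving out each array in turn. Both models were tested on simulated data with 61179 probe sets, 200 changed probe sets per simulation and 5 simulations. The simulated arrays held the same replicate difference in every group and the residual spread of the blocked model. The advantage of the blocked model in them was thus built in. For the stress effect averaged over genotypes, limma recovered 27.8% of changes of 0.5 on the log2 scale, 77.9% of changes of 1 and 95.8% of changes of 2. The blocked model recovered 63.0%, 94.6% and 99.4% of them. For Pavon-TL against both other genotypes, limma recovered 23.9%, 73.1% and 91.2% of those sizes, and the blocked model 55.8%, 93.4% and 99.7%. For the stress effect in Null Control alone, limma recovered 0.299%, 33.7% and 79.4%, and the blocked model 6.27%, 66.9% and 96.4%. Over the 5 simulations, false calls for the mean stress effect were 1 of 671 calls without the block and 44 of 900 with it. They were 2 of 628 and 30 of 859 for Pavon-TL, and 0 of 376 and 23 of 586 for stress in Null Control. The interactions were not simulated.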

Results

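Transcript levels were measured in roots of wheat seedlings of 3 genotypes under 2 water conditions, with 2 arrays per group. Pavon76 is a wheat cultivar. From what is known of the study outside the labels, Pavon-TL is a translocation line of Pavon76 with a chromosome segment from a wild wheat relative. The labels call the last genotype Null Control and do not describe it. It is treated here, with Pavon76, as a control for Pavon-TL. The array medians lay between 5.89 and 5.93 on the log2 scale. Arrays with the same replicate number in different groups correlated across probe sets with r between 0.991 and 0.996, and arrays of the same group with different numbers between 0.980 and 0.987. Probe sets are not independent replicates.

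**Figure D1:**
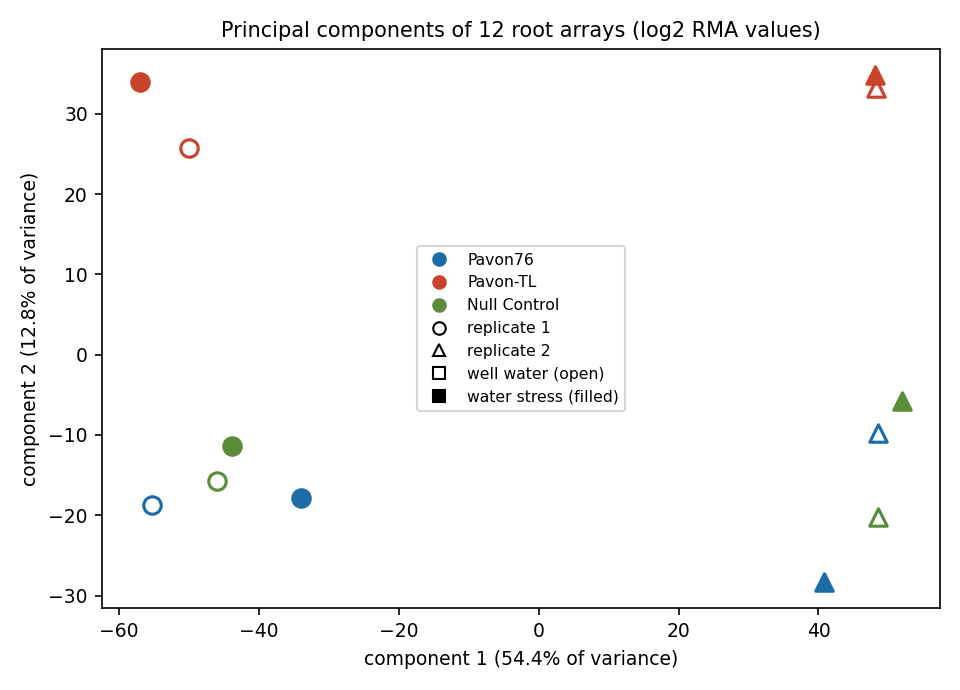
Principal components of the 12 root arrays (log2 RMA values), with component 1 (54.4% of the variance) on the x axis and component 2 (12.8%) on the y axis. Colours stand for genotypes, marker shapes for replicate numbers and filled markers for water stress; the replicate numbers lie on opposite sides of component 1 and the 4 Pavon-TL arrays at the top of component 2.

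The first question was which transcripts respond to watering every second day. Averaged over the 3 genotypes, dehydrins, LEA proteins, fructan enzymes, oxidative stress enzymes, defence genes and histones showed small differences, and 0 probe sets passed limma's test. An unadjusted p under 0.05 was reached by 2619 probe sets (4.28%). With the replicate number as a block, 5 probe sets passed, all higher under water stress, and 6173 (10.1%) had an unadjusted p under 0.05. Over the fixed lists, 1 of 106 probe sets passed in limma when adjusted over the list alone, and 7 with the block.

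The dehydrin and LEA list, proteins that accumulate as seeds and tissues dry, had 10 probe sets of 5 genes. Of these, 7 had positive and 3 negative differences, with 0 past the threshold over all probe sets (the smallest unadjusted limma p was 0.0565). The dehydrin Rab15 (LOC543293) averaged 8.41 ± 0.25 (SD, n = 6) under well water and 8.63 ± 0.22 (SD, n = 6) under water stress, a difference of 0.22 ± 0.13 (SE). Its 3 probe sets all had positive differences. Within Pavon76 its difference was 0.52 ± 0.22 (SE), so the mean difference came mostly from this genotype. The LEA protein Em (LOC543480) differed by -0.14 ± 0.09 (SE), and its 3 probe sets differed in sign, from -0.14 to 0.15. In Pavon76 the LEA gene PMA2005 (LOC543476) differed by -0.79 ± 0.41 (SE), while its mean under well water and water stress was 5.37 and 5.66 in Pavon-TL and 5.02 and 5.54 in Null Control. The list as a set gave a limma camera adjusted p = 0.459, with a median of 0.06.

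The cell division and chromatin list held 9 probe sets of 3 histone H2A genes, 3 with positive and 6 with negative differences. Its pattern did not match the symbol of the histone H2B gene wcH2B-8, described below. The histone wcH2A-2 (LOC732712) averaged 9.60 ± 0.21 (SD, n = 6) under well water and 9.25 ± 0.14 (SD, n = 6) under water stress, a difference of -0.34 ± 0.10 (SE) that did not pass over all probe sets. Adjusted over the list alone, its limma adjusted p was 0.0973, and 0.0166 with the block. The set had a median of -0.08 and a camera adjusted p = 0.251. Without the first Null Control well-watered array, its camera adjusted p was 0.0154, and 0.644 with an estimated correlation. The tubulins, which form microtubules and made up the reference gene list, had 1 positive and 9 negative differences over 10 probe sets, with a median of -0.10. Tubb4 (LOC543260) differed by -0.14 ± 0.06 (SE) and tubb3 (LOC543473) by -0.13 ± 0.07 (SE). As a set the tubulins gave a camera adjusted p = 0.0567, and 0.0370 with the block, and they passed under 7 of 21 alternatives. With an estimated correlation the adjusted p was 0.581, and 0.679 with the block, and the list passed under 0 of the 7 alternatives by camera.

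Of the 2 defence probe sets, wci (LOC542996) differed by 0.25 ± 0.07 (SE) and PR5 (LOC543292), a thaumatin-like protein, by -0.32 ± 0.16 (SE). Adjusted over the list alone, wci passed with a limma adjusted p of 0.0165, and PR5 only with the block, at 0.00961. Neither passed over all probe sets. The 11 probe sets of oxidative stress enzymes split into 6 positive and 5 negative differences. Catalase CAT1, which breaks down hydrogen peroxide, differed by -0.18 ± 0.07 (SE). The set's camera adjusted p was 0.821, and its test direction was down while its median was 0.02. Of 5 probe sets for fructan and sucrose enzymes, 1 was positive and 4 were negative, with a median of -0.06 and a camera adjusted p = 0.459. The fructan exohydrolase 6-FEH (LOC780575) differed by -0.04 ± 0.06 (SE) and the invertase IVR1 (LOC543415) by -0.08 ± 0.10 (SE).

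Lists of fewer than 5 probe sets were small in number and change. The cell wall enzyme XTH, a xyloglucan-modifying enzyme, differed by -0.20 ± 0.31 (SE). The small heat shock protein hsp16.9A (LOC543277) differed by -0.12 ± 0.12 (SE). The methyltransferase COMT1 (LOC543449) of the phenylpropanoid list differed by -0.16 ± 0.29 (SE). The ribosomal protein genes RPL9 and RPS29 differed by -0.02 ± 0.09 (SE) and 0.00 ± 0.50 (SE), and the other probe set of RPS29 by 0.07. The lipid transfer protein LTP3 (LOC543095) differed by 0.02 ± 0.06 (SE), and its other probe set by -0.03. The signs of XTH, COMT1, RPL9, RPS29 and LTP3 changed when 1 array was left out.

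Markers of other tissues were measured beside these groups. The leaf photosynthesis list had 31 probe sets, 28 of them for the Rubisco large subunit rbcl, with 18 positive and 13 negative differences. Its median was 0.02 and its camera adjusted p = 0.459. The rbcl probe set with the highest mean level differed by 0.28 ± 0.17 (SE), and the gene's probe sets ranged from -0.12 to 0.32. Adjusted over the list alone, 3 rbcl probe sets passed with the block (limma adjusted p = 0.0365, 0.0182 and 0.0317, against 0.519, 0.519 and 0.0991 without it), all with positive differences. The photosystem protein PsbP (LOC543290) differed by -0.11 ± 0.15 (SE), and its other probe set by 0.03. The grain storage list had 11 positive and 9 negative differences over 20 probe sets and a camera adjusted p = 0.821, with a median of 0.02 and a test direction of down. It was matched on gene symbols and includes GLU1A (LOC780595), a beta-glucosidase that is not a storage protein. The gliadin Gli-8 (LOC543211) differed by 0.37 ± 0.11 (SE) and the gliadin Gli-Z5 (LOC543210) by -0.20 ± 0.10 (SE). Adjusted over the list alone, Gli-8 passed only with the block (limma adjusted p = 0.0179, against 0.227 without it). The grain serpin Serpin-Z2B (LOC543382), a protease inhibitor, differed by 0.19 ± 0.06 (SE).

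**Figure D2:**
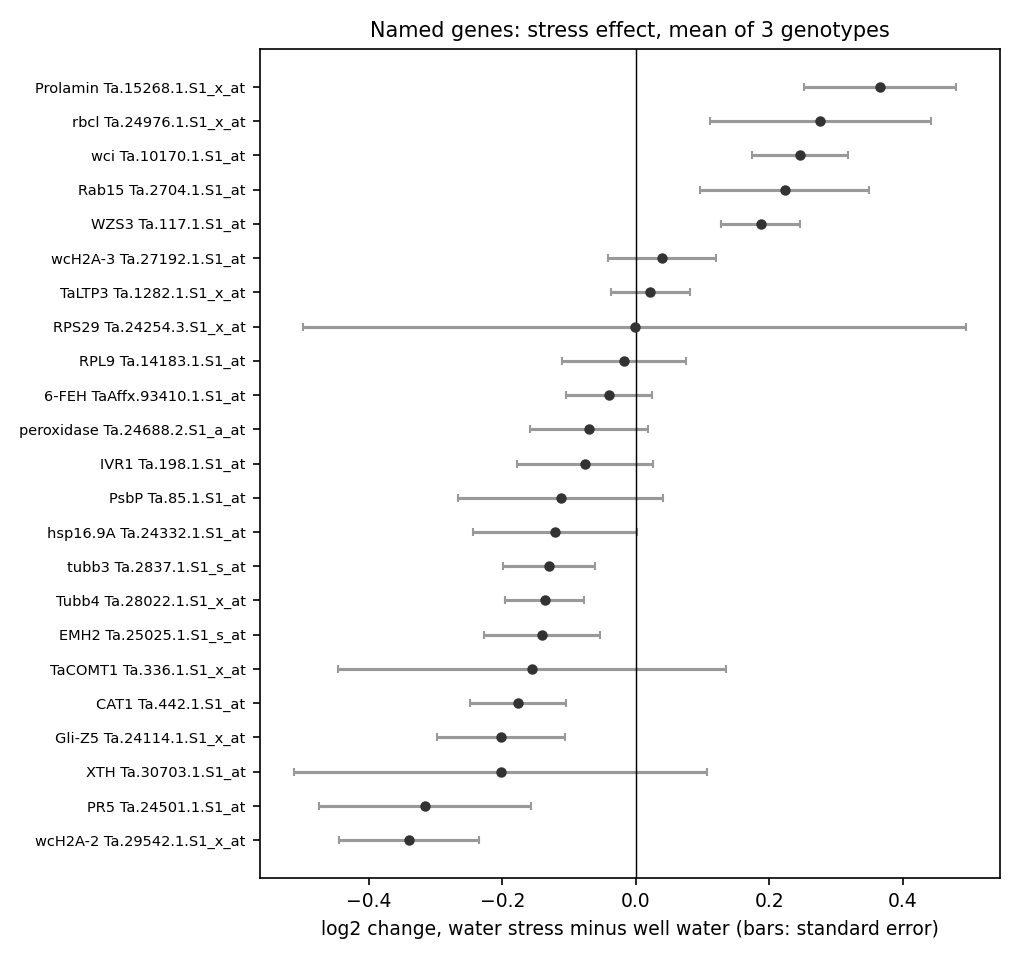
Difference between water stress and well water on the log2 scale (x axis), averaged over 3 genotypes, for each named gene with its probe set (y axis); points are limma estimates and bars are standard errors. The values run from -0.34 for wcH2A-2 to 0.37 for a gliadin, labelled Prolamin, and none of the genes passed the threshold over all probe sets.

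The 5 probe sets that passed with the block have no gene name here and were chosen after their values were seen. The one with the smallest p rose by 1.13 ± 0.09 (SE, blocked limma adjusted p = 0.00712). In Pavon76 its mean was 5.82 under well water and 6.77 under water stress. It was 5.33 and 5.72 in Pavon-TL, and 5.50 and 7.54 in Null Control, where the rise was largest. This probe set also counts among those that differed in Pavon-TL, described below. The others rose by 1.16 ± 0.11, 0.76 ± 0.08, 0.74 ± 0.08 and 0.64 ± 0.07 (SE). Without the block their limma adjusted p-values ranged from 0.355 to 1.00. With the block and 1 array left out, an alternative chosen after seeing the data, the count ranged from 0 (without the first Pavon76, or either Null Control, well-watered array) to 35 (without the second Pavon-TL stressed array).

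Within single genotypes the stress comparison gave 0 probe sets past limma's threshold in each. An unadjusted p under 0.05 was reached by 1737 probe sets in Pavon76, 1532 in Pavon-TL and 2090 in Null Control. With the block, Pavon76 and Pavon-TL again gave 0, with 4017 and 3666 at an unadjusted p under 0.05. Null Control gave 1 with the block, with 5124 at an unadjusted p under 0.05. That probe set is the one with the smallest p above, at 5.50 ± 0.07 (SD, n = 2) under well water and 7.54 ± 0.02 (SD, n = 2) under water stress, with a blocked limma adjusted p = 0.00458 and 0.250 without the block. In Pavon76 the named genes with the smallest p were wci at 0.33 ± 0.12 (SE), Rab15, CAT1 at -0.28 ± 0.12 (SE), PMA2005 and the thionin gene (LOC543413) at -0.25 ± 0.13 (SE). In Pavon-TL they were Gli-8 at 0.50 ± 0.20 (SE), Gli-Z8 (LOC543385) at -0.39 ± 0.17 (SE), wcH2A-2 at -0.36 ± 0.18 (SE), PEAMT1 (LOC543067) at -0.28 ± 0.15 (SE) and the amylase inhibitor WMAI-1 (LOC542981) at -0.28 ± 0.16 (SE). In Null Control they were wcH2A-2 at -0.53 ± 0.18 (SE), Serpin-Z2B at 0.29 ± 0.10 (SE), avnla (LOC780582) at -0.46 ± 0.19 (SE), Em at -0.34 ± 0.15 (SE) and wci at 0.28 ± 0.12 (SE). None of these passed.

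Across probe sets the stress differences correlated at 0.0673 between Pavon76 and Pavon-TL, 0.151 between Pavon76 and Null Control, and 0.248 between Pavon-TL and Null Control. Probe sets with the same sign in all 6 pairs of arrays with the same genotype and number made up 5.37% of those tested, against 3.13% by chance. The mean difference reached 2-fold in 16 probe sets, of which 4 had the same sign in the 6 pairs.

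The next question was how roots of Pavon-TL differ from those of the control genotypes. Averaged over both water conditions, 122 probe sets passed limma's threshold between Pavon-TL and the mean of Pavon76 and Null Control, of which 99 were lower and 23 higher in Pavon-TL. Lower probe sets thus made up 81.1% of the calls (exact binomial 95% interval 73.1% to 87.7%, which treats probe sets as independent). The median change was -2.15 among the lower and 0.94 among the higher ones. A change of at least 16-fold was found in 22 lower and 2 higher probe sets. Only 3 called probe sets carried a gene annotation, and all 3 were lower in Pavon-TL. With the block, 388 passed, 207 higher and 181 lower, so 46.6% were lower. With the block and 1 array left out, an alternative chosen after seeing the data, the count ran from 208 (68 higher, 140 lower, without the second Pavon-TL well-watered array) to 594 (373 higher, 221 lower, without the second Pavon-TL stressed array). The balance of higher and lower blocked calls thus turned with the array left out.

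LOC543418 averaged 3.57 ± 0.28 (SD, n = 4) in Pavon-TL and 10.88 ± 0.38 (SD, n = 8) in the controls. Its signal was lower by 7.30 on the log2 scale (limma adjusted p = 2.10e-06). Its Pavon-TL mean lies below the first quartile of all values (4.34) and was not shown to lie above background. LOC780661 averaged 4.69 ± 0.40 (SD, n = 4) in Pavon-TL and 10.82 ± 0.10 (SD, n = 8) in the controls, a signal lower by 6.13 (limma adjusted p = 2.70e-07). A sequence difference under the probes could also lower these signals, so the size of any fall in transcript is not known. The annotation gives no further name for either gene. A probe set of the histone H2B gene wcH2B-8 (LOC543184) averaged 11.72 ± 0.20 (SD, n = 4) in Pavon-TL and 12.61 ± 0.15 (SD, n = 8) in the controls, and fell by 0.89 ± 0.10 (SE, limma adjusted p = 0.00974). The other 6 probe sets of wcH2B-8 did not pass, with differences from -0.21 to -0.04. The one that passed is marked as cross-hybridizing. An unnamed probe set of the same transcript cluster differed by -5.42 under well water and -5.58 under water stress. The fall of 0.89 may thus not come from this gene. The wcH2B-8 call was lost without the second Pavon-TL well-watered array (adjusted p = 0.0745) or the second Pavon-TL stressed array (adjusted p = 0.0613). Its limma adjusted p ranged from 0.00108 to 0.0745 over the alternatives.

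Among unnamed probe sets with large falls, whose order depends on their floors, the first averaged 4.04 ± 0.61 (SD, n = 4) in Pavon-TL and 11.64 ± 0.54 (SD, n = 8) in the controls. Another averaged 3.95 ± 0.23 (SD, n = 4) and 11.49 ± 0.33 (SD, n = 8). Of the unnamed probe sets with large rises, the first averaged 8.81 ± 0.23 (SD, n = 4) in Pavon-TL and 3.20 ± 0.19 (SD, n = 8) in the controls, and another 9.12 ± 0.30 (SD, n = 4) and 4.43 ± 0.14 (SD, n = 8). Of the 99 lower probe sets, 64 had a Pavon-TL mean below 5.91, the median of all values, while 9 had a control mean below it. The 4 Pavon-TL arrays lay entirely outside the 8 control arrays in 114 of the 122. Over all tested probe sets this held for 412 (0.673%).

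**Figure D3:**
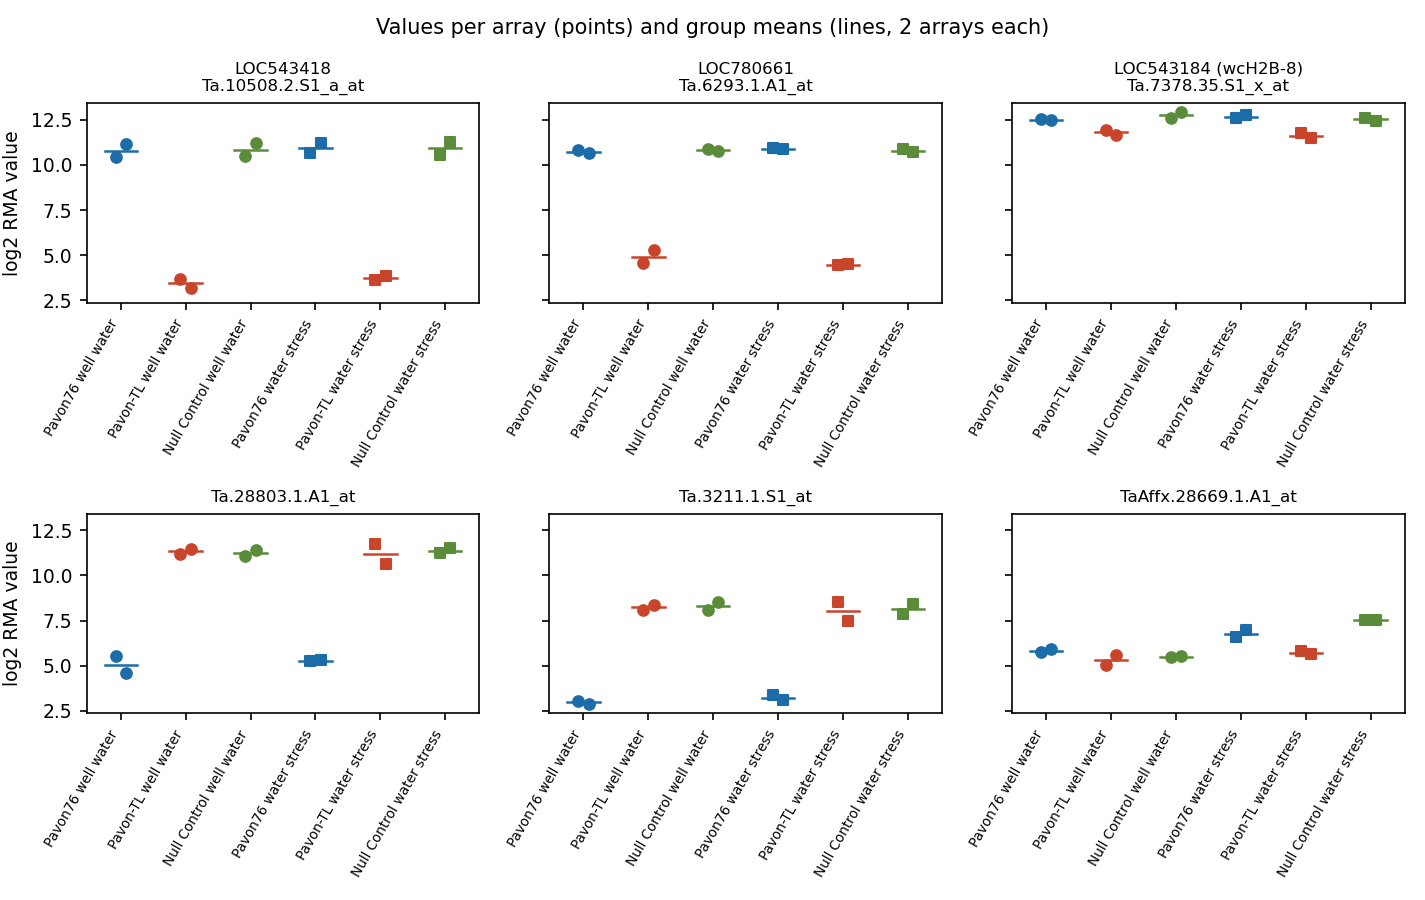
Log2 RMA values (y axis) of 6 probe sets in each of the 6 groups (x axis); points are single arrays, circles for well water and squares for water stress, and lines are means of 2 arrays. LOC543418 and LOC780661 lie near 11 in the controls and below 5.5 in Pavon-TL, while the first and second panels of the lower line, for unnamed probe sets, show low values in Pavon76 alone.

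Named genes of the stress, defence and metabolism lists showed small differences between Pavon-TL and the controls. Of the 106 probe sets on the fixed lists, which do not hold wcH2B-8, 0 passed in limma over all probe sets. Adjusted over the list alone, 0 passed without the block and 1 with it. The smallest unadjusted p was 0.0323, and 2422 of all tested probe sets had an unadjusted p under 0.05. The dehydrin and LEA list had 3 positive and 7 negative differences, a median of -0.09 and a camera adjusted p = 0.886. Its member COR410, a dehydrin, differed by -0.08 ± 0.08 (SE), and EM (LOC543497) by 0.06 ± 0.06 (SE), with its other probe set at -0.01. The oxidative stress enzymes had 4 positive and 7 negative differences, with a median of -0.03, a test direction of up and a camera adjusted p = 0.886. CAT1 differed by 0.18 ± 0.08 (SE) and the peroxiredoxin Prx1 (LOC606328) by 0.18 ± 0.08 (SE), while the 4 probe sets of Prx1 split into 2 positive and 2 negative values. Fructan and sucrose enzymes had 3 positive and 2 negative differences, with a median of 0.01, a test direction of down and a camera adjusted p = 0.896. The fructan exohydrolase 1-FEH (LOC543441) differed by -0.11 ± 0.10 (SE).

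The H2A list had 2 positive and 7 negative differences (median -0.03, camera adjusted p = 0.886), and the tubulins 4 and 6 (median 0.00, camera adjusted p = 0.896). The leaf list had 16 positive and 15 negative differences and the grain list 10 of each, both with a camera adjusted p = 0.886. In the grain list, granule-bound starch synthase GBSS-I (LOC543395) differed by -0.21 ± 0.11 (SE) and BMY1 (LOC543318) by -0.26 ± 0.13 (SE). BMY1 in Pavon-TL was close to Null Control, so its difference comes mostly from Pavon76. The largest named difference that did not pass was that of lgul (LOC542984), at -0.88 ± 0.37 (SE). Its mean was 3.77 in Pavon-TL and 3.88 in Null Control, against 5.41 in Pavon76, so the difference comes from Pavon76. XTH differed by -0.35 ± 0.33 (SE), PR5 by 0.12 ± 0.17 (SE) and wci by -0.07 ± 0.08 (SE). The sign for PR5 changed without the second Pavon-TL well-watered array. RPS29 (LOC606342) differed by 0.66 ± 0.53 (SE) and passed with the block only when adjusted over the list alone, with a limma adjusted p = 0.0309. The other probe set of RPS29 differed by -0.06.

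Further annotated genes passed with the block alone, all higher in Pavon-TL averaged over the water conditions. For LOC542989, 2 probe sets did so, at 1.52 ± 0.22 (SE) and 0.69 ± 0.12 (SE). For LOC606326, 2 did so, at 0.82 ± 0.10 (SE) and 0.68 ± 0.11 (SE). LOC100037518 differed by 0.65 ± 0.11 (SE), LOC100049023 by 0.67 ± 0.12 (SE) and LOC543236 by 0.45 ± 0.08 (SE). Their blocked limma adjusted p-values ranged from 0.00241 to 0.0488.

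The Pavon-TL difference was also tested in each water condition. Under well water 78 probe sets passed limma's threshold, 68 lower and 10 higher. Under water stress 81 passed, 69 lower and 12 higher. Of these calls 72 were shared. The arrays of the 2 conditions differ, but both comparisons use the same genotypes and 1 fit with a common spread per probe set. The overlap is therefore not an independent replication. The 0.0787 expected to be shared in the same direction for independent lists of those sizes is no reference for it. With the block the counts were 138 (115 lower, 23 higher) and 284 (126 lower, 158 higher). LOC543418 and LOC780661 passed in both conditions. wcH2B-8 passed under water stress only with the block (limma adjusted p = 0.00945, against 0.0659 without it). All 78 well-water calls had the same direction under water stress, and all 81 water-stress calls under well water. Under well water the named genes with the smallest p were the anther gene raftin1a (LOC543442), at -0.28 ± 0.12 (SE), GBSS-I, PCS1 (LOC542834), a phytochelatin synthase, at -0.45 ± 0.24 (SE), BMY1 and lgul, none of which passed. Under water stress they were the zinc finger gene WZF1 (LOC543182), at 0.94 ± 0.44 (SE), another wcH2B-8 probe set at -0.26 ± 0.12 (SE), CAT1 at 0.20 ± 0.11 (SE), and the gibberellin oxidases Ta20ox1B (LOC543326) and Ta20ox1A (LOC543327), at -0.32 ± 0.18 (SE) and -0.34 ± 0.21 (SE), none of which passed. The well-water count was 45 or 43 without either Pavon-TL well-watered array and 41 with only the arrays compared. The water-stress count was 49 without the first Pavon-TL stressed array.

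**Figure D4:**
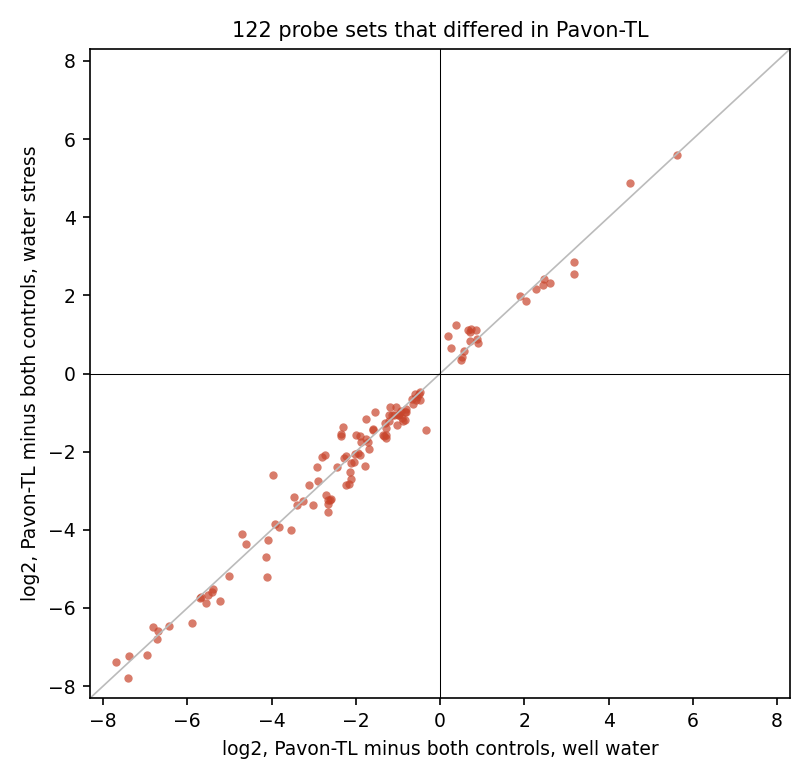
Difference between Pavon-TL and the mean of both control genotypes on the log2 scale under well water (x axis) and water stress (y axis) for the 122 probe sets that passed limma's threshold averaged over both conditions; the grey line marks equal values. The points lie along that line, with a median difference between the conditions of 0.18 in size.

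Whether Pavon-TL responds to water stress differently from the controls was tested by the interaction. It gave 0 probe sets past limma's threshold, with 1080 at an unadjusted p under 0.05, and 0 with the block, with 2857. Among the 122 probe sets that differed in Pavon-TL, 9 had an unadjusted interaction p under 0.05 and 0 passed after adjustment within the 122. The avenin-like gene avnla had an interaction of 0.48 ± 0.24 (SE). HGGT (LOC543094), of vitamin E synthesis, had one of -0.39 ± 0.19 (SE), raftin1a of 0.32 ± 0.17 (SE), Gli-Z8 of -0.38 ± 0.21 (SE) and Ta20ox1B of -0.39 ± 0.25 (SE). Rab15 had an interaction of -0.26 ± 0.27 (SE) and COR410 of 0.22 ± 0.16 (SE), and the dehydrin and LEA list a median of 0.02. The probe sets of Rab15 ranged from -0.26 to 0.23 and those of raftin1a from -0.11 to 0.32. The sign for Rab15 changed without the second Pavon-TL well-watered array. The 7 tested lists had a camera adjusted p = 0.993 each. Without the second Pavon-TL well-watered array, the adjusted p of the tubulins was 0.0106, and 0.936 with an estimated correlation. Over the list alone 0 of 106 probe sets passed in limma, with or without the block. The interaction between Null Control and Pavon76 gave 0 as well, with 1648 at an unadjusted p under 0.05, and 0 with the block, with 3757.

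Against each control genotype alone, Pavon-TL differed in 103 probe sets from Pavon76 (84 lower, 19 higher) and in 93 from Null Control (80 lower, 13 higher). With the block the counts were 305 (179 lower, 126 higher) and 352 (159 lower, 193 higher). The wcH2B-8 probe set fell by 0.87 against Pavon76 (limma adjusted p = 0.0316) and by 0.91 against Null Control (limma adjusted p = 0.0262). It passed under 7 of 19 alternatives against Pavon76 and 6 of 19 against Null Control, with an adjusted p of up to 0.204 and 0.196. The gene lgul averaged 3.77 ± 0.54 (SD, n = 4) in Pavon-TL and 5.41 ± 0.48 (SD, n = 4) in Pavon76, a difference of -1.64 that passed only with the block (limma adjusted p = 0.0214, against 0.830 without it). Its Pavon-TL mean lies below the first quartile of all values (4.34) and was not shown to lie above background. The lectin WGA2 (LOC543494), chosen after its values were seen, differed by -0.94 from Pavon76 and also passed only with the block (limma adjusted p = 0.0425, against 1.00 without it). BMY1 differed by -0.48 ± 0.15 (SE) from Pavon76, and Prx1 by 0.23 ± 0.09 (SE) and WZF1 by 0.79 ± 0.36 (SE) from Null Control, which did not pass.

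The control genotypes were compared as the background for these differences. Null Control differed from Pavon76 in 3 probe sets by limma and in 9 with the block, all higher in Null Control. The 3 have no gene name and were chosen after their values were seen. The first averaged 11.32 ± 0.19 (SD, n = 4) in Null Control and 5.16 ± 0.40 (SD, n = 4) in Pavon76. The second averaged 8.22 ± 0.30 (SD, n = 4) and 3.09 ± 0.20 (SD, n = 4), and the last 7.82 ± 0.09 (SD, n = 4) and 3.75 ± 0.16 (SD, n = 4). In Pavon-TL these probe sets averaged 11.26, 8.13 and 7.74, close to Null Control. They count among the 122 because the control mean includes Pavon76. Another of the 122, which differed between the controls only with the block, averaged 3.83 in Pavon76, 7.42 in Pavon-TL and 6.55 in Null Control. Its difference in Pavon-TL thus also comes largely from Pavon76. Among named genes that did not pass, lgul differed by -1.52 ± 0.43 (SE), with a Null Control mean below the first quartile of all values. BMY1 differed by -0.45 ± 0.15 (SE), the serpin Serpin-Z1C (LOC542985) by 0.22 ± 0.11 (SE) and the peroxidase PER1 (LOC543108) by -0.21 ± 0.11 (SE), which did not pass either. The count was 6 without the first Null Control stressed array.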

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

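The test of the spiked control transcripts against water condition, the tests of the chromosome segment and of other explanations for the split by replicate number, the comparison of other Affymetrix control transcripts, both tests of other splits for the stress effect, the splits that part all pairs, and the choices of clusters and siblings in the sibling test were chosen only after the results were seen. The other tests reported here were chosen before.

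The spiked hybridization controls, which are added in equal amounts to each array and were not used in any comparison, read higher under water stress. Their 21 probe sets averaged 9.31 under water stress and 8.94 under well water, a difference of 0.37 ± 0.26 (SD of 6 pairs). The difference was positive in 5 of 6 pairs (exact two-sided sign-flip p = 0.0625, where the smallest possible is 0.03125). The poly-A controls, added before labelling, differed by -0.03 ± 0.17 (SD of 6 pairs, exact p = 0.719). The ubiquitin and sucrose synthase control transcripts of wheat were higher by 0.12 each in 6 of 6 pairs (exact p = 0.03125, adjusted 0.109 over 7 transcripts), which did not pass the correction.

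Other splits of the arrays were used to ask whether chance can be excluded for each count. For the stress effect averaged over genotypes, the real count was 0, which all 100 of 100 drawn splits reach by construction, so their share decides nothing. The highest other count, 15944, came from a split that follows the replicate number in 3 genotypes, as did the next ones (950 and 480), which points to a structure of the samples and not to water. The 4 drawn splits of that kind gave 423 to 15944, and 30 splits that balanced the numbers in each genotype gave 0. With the block, the real exchange of water labels was the only one of 32 to give 5, against at most 3. That test was chosen after the count was seen and was not corrected for the other split tests, so it does not exclude chance for that count.

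For Pavon-TL against both controls, 2 of 100 drawn splits gave at least 122, a share under 0.05. The other was a split that follows the replicate number (7445), and the next highest gave 59. With the block, 1 of 81 splits, the real one, gave 388, against at most 176, also a share under 0.05. Both shares speak only against a chance assignment of the genotype labels to these arrays. They cannot exclude chance differences between the plants sampled, since the arrays of a group may not come from separate plants. The comparisons of 4 against 4 arrays were split in a simpler fit with 1 term for water, whose counts differ slightly from those of the model with all groups. There, 2 of 35 splits gave at least the real count for Pavon-TL against Pavon76 (118 in that fit), Pavon-TL against Null Control (104) and Null Control against Pavon76 (5). In each, the other split follows the replicate number (6098, 7530 and 1922), and only for that reason the share over all splits does not exclude chance. The next highest counts were 0, 0 and 4. Arrays of the same water condition and replicate number form 4 pairs, all parted by the real split and 0 of them by the split that follows the number. Of the 8 splits that part all 4 pairs, the real 1 gave the highest count in each comparison, and the others gave 0, but 8 splits are too few for a share under 0.05. The blocked counts were 305, 352 and 9.

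A pattern to follow up is the loss of signal in Pavon-TL, where 63 probe sets were lower in both water conditions. Sequence differences under single probe sets could lower a signal without a change in transcript level, and then other probe sets of the same transcript cluster would keep their level. By the test as planned, 14 of 67 such siblings (20.9%, exact 95% interval 11.9% to 32.6%) were lower by at least 1 on the log2 scale. The prediction made beforehand was that mismatch would leave under 50% of them lower, so the planned test came out for mismatch. Without the largest cluster, left out after that result was seen, 14 of 31 were lower (45.2%, interval 27.3% to 64.0%). These counts include siblings that are themselves among the 63. With 1 lower probe set per cluster set aside, 13.1% of 61 siblings (interval 5.84% to 24.2%) were lower by as much, but 36 came from 1 cluster. Without it, 8 of 25 were (32.0%, interval 14.9% to 53.5%). Of these 8, 7 are themselves among the 63, and of 54 siblings outside the 63 only 1 was lower, a count that leaves out most lower siblings by its choice. The planned outcome rested on the largest cluster. The intervals without that cluster include 50% in both versions, so mismatch and lower transcript levels cannot be told apart here. Siblings that report copies on other wheat genomes may also keep their level. The published chromosome segment, known from outside the labels, is another explanation. Of 8 annotated genes that passed with the block, 4 lie in its homoeologous chromosome group, counted over all wheat genomes. Of 761 annotated genes with a chromosome, 113 lie there (odds ratio 5.89, interval 1.08 to 32.1, Fisher's exact p = 0.0200). Of the 4, LOC780661 and wcH2B-8 (by a probe set marked as cross-hybridizing) were lower in Pavon-TL, while LOC542989 and LOC543236 were higher. LOC543418, the annotated gene with the largest drop in signal, was not among them. The test thus does not bear on the loss of signal alone. A link to the segment is a hypothesis from few genes, since without the block it was 2 of 3 genes (Fisher's exact p = 0.0592).

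The other pattern is the split of all arrays by replicate number. A difference in labelling or hybridization between batches cannot be told apart from other causes. The spread of the change over 69 spiked probe sets was 0.194 times that over wheat probe sets of like level (bootstrap interval 0.135 to 0.256), which goes against it. The poly-A spikes, however, were higher in replicate 2 in 6 of 6 groups, by 0.07 to 0.47 (exact p = 0.03125), while the hybridization spikes were higher in only 3 of 6 (0.12 ± 0.22, SD of 6 groups, exact p = 0.281). With the mean shift of all spiked probe sets kept, the ratio of root mean squares was 0.420 (0.314 to 0.513). Leaf or grain tissue in 1 set of roots stays open too. Most leaf probe sets read near the floor (median level 3.85), and over the 6 leaf and 4 grain probe sets above the median level the median changes were 0.27 and 0.289, against a median size of 0.42 among the probe sets that differed. The grain median includes GLU1A (LOC780595, 0.35), a beta-glucosidase that was matched by its symbol and is not a grain storage protein. The remaining grain probe sets above the median level changed by 0.23, 0.03 and 0.40. Of the leaf probe sets 5 passed as higher and 1 as lower in replicate 2 (limma), among them PsbO at 0.62 and the rbcl probe set with the highest mean level at 0.43, while another rbcl probe set changed by -0.39. RNA degradation also cannot be told apart from other causes: the 5' minus 3' level changed by 0.37 ± 0.31 (SD, n = 6 groups) for actin and by -0.19 ± 0.23 (SD, n = 6 groups) for GAPDH, both dim at the 3' end (5.04 and 4.72). Of the brighter transcripts, ubiquitin changed by -0.11 ± 0.10 (SD, n = 6 groups) and was lower in 6 of 6 groups, glucose-6-phosphate dehydrogenase by -0.22 ± 0.23 (SD, n = 6 groups) and sucrose synthase by -0.07 ± 0.48 (SD, n = 6 groups). CYP86 changed by -0.17 and EF1a by 0.15, so the transcripts went both ways. No biological explanation was tested, and a difference in growth, harvest or time between the replicate sets stays open.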

How the results depend on the processing

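The combinations of the block with an array left out, and of an estimated correlation with the other alternatives, were chosen after seeing the data, and all other alternatives here were planned. Counts of calls stayed within 1.5 times under 103 of 114 combinations of result and alternative, and under 146 of 156 omissions of 1 array. Many of these are stress and interaction counts of 0 that stayed 0. Named genes kept direction and side of the threshold in 781 of 788 combinations and 1315 of 1404 omissions. Of the others, 4 and 23 lost their call, 1 gained it with the block, and 2 and 66 changed sign. Nearly all of these gene results had not passed to begin with, so keeping their side says little. Without the block the only gene with a name that passed was wcH2B-8, and the lost calls were its own. Gene lists kept direction and side of the threshold in 141 of 165 combinations and 194 of 252 omissions. Of the other list results, 2 and 7 gained a call and 22 and 51 changed direction. In 0 of the 141 changes of sign or direction had the value passed limma's or camera's threshold before or after.

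The block on the replicate number gave 388 probe sets for Pavon-TL against both controls (122 without it), 138 (78) under well water and 284 (81) under water stress, 305 (103) against Pavon76, 352 (93) against Null Control, 9 (3) for Null Control against Pavon76, 5 (0) for the mean stress effect, 1 (0) for stress in Null Control and 1 (0) gene list. All calls without the block were also made with it. Among genes with a name, lgul and WGA2 against Pavon76 and wcH2B-8 under water stress passed only with the block. A fit of only the well-watered arrays gave 41 for Pavon-TL, with fewer arrays to estimate the spread. With dim probe sets left out, 1 gene list (tubulins, stress) passed, with an adjusted p of 0.0395, and 0.528 with an estimated correlation. The 9 list calls under all alternatives had an adjusted p of 0.471 to 0.936 with an estimated correlation, so 0 passed in camera. The cause was not tested for the other changes.

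With each array left out in turn, Pavon-TL against both controls gave 85 to 107, 43 to 75 under well water and 49 to 75 under water stress. Pavon-TL gave 75 to 98 against Pavon76 and 70 to 90 against Null Control, and Null Control against Pavon76 gave 3 to 6. All stress and interaction counts were 0 by limma, and gene lists 0 to 2. The lone array left in a group was assumed to vary like the others. With the block and an array left out, Pavon-TL against both controls gave 208 to 594.

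Signs of genes that had not passed changed mostly with an array left out. For the mean stress effect the values then ran from -0.491 to 0.085 for XTH, -0.143 to 0.00086 for PER1, -0.0055 to 0.049 for LTP3, -0.322 to 0.010 for COMT1, -0.017 to 0.095 for wcH2A-3, -0.068 to 0.032 for RPL9 and -0.413 to 0.409 for RPS29. For Pavon-TL against both controls they ran from -0.202 to 0.146 for hsp16.9A, -0.063 to 0.294 for PR5, -0.184 to 0.305 for COMT1, -0.111 to 0.057 for wcH2A-3 and -0.113 to 0.240 for PsbO. For the interaction they ran from -0.531 to 0.019 for Rab15, -0.636 to 0.277 for GSTZ1, -0.118 to 0.577 for hsp16.9A, -0.412 to 0.303 for PR5, -0.073 to 0.0090 for LTP3 and -0.596 to 0.383 for COMT1. They further ran from -0.017 to 0.083 for wcH2A-9, -0.173 to 0.103 for wcH2A-2, -0.017 to 0.278 for RPL9, -0.688 to 1.78 for RPS29, -0.425 to 0.034 for PsbP, -0.132 to 0.574 for PsbO, -0.394 to 0.023 for Tubb5 and -0.182 to 0.045 for tubb1. Under median and MAD scaling wcH2A-3 was 0.0094 against both controls, and wcH2A-9 -0.0043 in the interaction.

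Directions of gene lists changed as well, and are given here by camera adjusted p. With dim probe sets left out these were oxidative stress enzymes (0.876) and grain markers (0.242) for stress, tubulins (0.964) for Pavon-TL, and dehydrins, leaf and grain markers (0.956 each) for the interaction. With 1 probe set per gene they were dehydrins and tubulins (0.994 each) for Pavon-TL and grain markers (0.463) for the interaction. Under median and MAD scaling they were the H2A list (0.912) and tubulins (0.660) for Pavon-TL, and leaf and grain markers (0.990 each) for the interaction. After quantile normalization they were dehydrins and leaf markers (0.984 each) for the interaction. Without cross-hybridizing probe sets they were grain markers for stress (0.887) and the interaction (0.667). With the block they were oxidative stress enzymes (0.843) for stress, tubulins (0.897) for Pavon-TL, and dehydrins, leaf and grain markers (0.991 each) for the interaction.

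With an array left out, the adjusted p of lists that changed direction ran from 0.530 to 0.920 for oxidative stress enzymes and 0.488 to 0.944 for grain markers under stress. For Pavon-TL it ran from 0.628 to 0.982 for fructan enzymes, 0.325 to 0.935 for oxidative stress enzymes, 0.221 to 0.979 for the H2A list, 0.325 to 0.986 for grain markers and 0.207 to 0.998 for tubulins. For the interaction it ran from 0.609 to 0.998 for dehydrins, leaf and grain markers, 0.609 to 0.985 for oxidative stress enzymes, 0.599 to 0.998 for the H2A list and 0.0106 to 0.985 for tubulins.

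Another scaling moved the median of all probe sets by at most 0.020 on the log2 scale and the share of lower calls by at most 1.98 points. The deposited values had already been quantile normalized between arrays, so a small effect of another scaling was largely set in advance. Comparisons of all 12 arrays have no separate fit of only the arrays compared, and dim or cross-hybridizing probe sets give no value where they were left out. Signal over background was not analysed here, so it is not known which low values carry signal.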

Other observations

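The comparison of the replicate numbers was chosen only after the arrays were seen to separate by them. The replicate sets differed in 16981 probe sets by limma in the model with a term for each group, of which 8984 were higher and 7997 lower in replicate 2, and 1688 changed by at least 2-fold. Among genes with a name, 20 were higher and 19 lower. DMAS1 (LOC100037594), which makes deoxymugineic acid for iron uptake, fell from 11.82 ± 0.59 (SD, n = 6) in replicate 1 to 9.56 ± 0.39 (SD, n = 6) in replicate 2 (limma adjusted p = 5.21e-05). The alpha-tubulin TUBA changed by -1.41, the immunophilin FKBP70 (LOC543314) changed by -1.34 and RPS29 by -1.30. COMT1 changed by -0.82.

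Higher in replicate 2 were the lectin WGA2 (LOC543494), which rose by 1.99 ± 0.14 (SE), and the xylanase inhibitor XIP-I (LOC542997), which rose by 1.60 ± 0.16 (SE). TaALMT1 (LOC543388), the aluminium-activated malate transporter of root tips, rose by 0.86 ± 0.09 (SE). petC rose by 0.85, GAPN by 0.75 and PsbO by 0.62. Of the 7 tested lists, the tubulins passed, with a median of -0.13 and a camera adjusted p = 0.0153, and did not with an estimated correlation (adjusted p = 0.884). The dehydrin and LEA list had a median of 0.00 and a camera adjusted p = 0.838.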
